A study of Mus musculus with 34 samples.

How the data were processed

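RNA was sequenced from 34 libraries of mouse cells: 17 of epiblast stem cells (EpiSC, the primed pluripotent state) and 17 of definitive endoderm (DE) made from them. The lines came from 7 inbred strains that are founders of mouse mapping populations; lines of 129S1/SvImJ were not analysed here. EpiSC were grown on irradiated mouse embryonic fibroblasts with FGF, activin at 20 ng/mL and a tankyrase inhibitor. Endoderm was made over 40 h, with 16 h in the GSK3 inhibitor CHIR at 3 uM and activin at 40 ng/mL, then 24 h in activin at 100 ng/mL with the BMP receptor inhibitor LDN-193189 at 100 nM, and cells bearing CXCR4 were taken with magnetic beads. Per the labels' protocols, EpiSC libraries were made with a stranded polyA kit and DE libraries with a low-input cDNA amplification kit (12 cycles of amplification), and both were read as pairs of 100 nt. The kit therefore splits the libraries as cell type does, and effects of kit and of cell type cannot be told apart.

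The values used are counts of reads per gene as deposited by the authors, whole numbers that were not normalised. Per the submitters' processing notes, reads were aligned with STAR 2.4 to mm10 and counted with HTSeq 0.6.1, and DESeq2 is named with no version. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Genes with near-identical copies are therefore reported as uncertain, and reads of a gene and its antisense or overlapping partner may be mixed. Every table held 53655 genes, and 0 entries named no gene. Coordinates are GRCm38 (mm10) positions from GENCODE M21, which gave a position for 28534 symbols. Totals ran from 25.6 to 33.8 M (mega) counts in EpiSC and from 23.8 to 67.7 M in DE. PCR reads without molecular identifiers are not independent molecules.

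Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, robust quasi-likelihood fit and quasi-likelihood F test, Benjamini-Hochberg adjustment, threshold 0.05) on genes with at least 10 counts in at least 3 libraries. All 34 libraries entered the fit of DE against EpiSC, with strain as a term, and the fits for interactions. Strain contrasts were fitted within each cell type on its 17 libraries, so that all strains shared 1 estimate of the spread. This takes the spread as equal between strains, which it was not in EpiSC, as given with the alternatives. Strain F tests used the 5 strains with 2 or more lines in both cell types, and strains with 1 line in a cell type were not compared there. Within a cell type each library is a separate cell line, so p-values of the strain contrasts measure the spread between lines. In the fits of all 34 libraries, the EpiSC and DE libraries of the 16 lines with both were treated as independent. The lowest chi-square per degree of freedom between replicate libraries was 6.57 in EpiSC and 31.5 in DE. No pair of libraries of the same strain and cell type was therefore a duplicate within sampling noise, and other pairs were not compared.

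A total of 24 gene lists was fixed before the data were examined. Counts of their members are over all genes tested, and the count adjusted over the list alone is given where it differs. They were tested with camera from limma 3.58.1 (preset correlation 0.01), with an estimated correlation, and with fry. The mean log2 CPM of each list (prior count of 2) was compared across strains with a permutation test of F (100000 resamples, adjusted over 48 tests). Genes named in the text are list members, or were ranked by a rule also fixed before the data were examined: for DE against EpiSC, the 8 largest log2 folds in each direction among genes with an adjusted p under 0.05, a mean log2 CPM of at least 4 and the same direction in all 16 lines with both libraries. For PWK/PhJ they were the 8 largest in each direction, and for each other strain the 2 largest, with a mean log2 CPM of at least 3 and no overlap between the libraries of the strains. For the difference of the PWK/PhJ effect between cell types they were the 5 largest in each direction, and for each F test the 6 smallest p-values. Predicted genes were passed over. A result on 1 list member is not reported here. In the results of the comparisons, list members with very few counts in a compared group were left unnamed once this was seen. Ranked genes of that kind that are named there are given as summed counts. The results flagged for a closer look name some such genes with log2 values and state that limit.

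Each line gives both an EpiSC and a DE library in 16 cases, and the line pairs them by origin. Deviations from the group means were correlated between the libraries of a line with r from -0.033 to 0.295 over 14 lines (median 0.07, above 0.1 in 6). The median was -0.048 for other lines of the strain, which is no independent comparison. In a strain with 2 lines that value is the same-line r with its sign reversed, and both lines share 1 r (0.263 in WSB/EiJ, 0.048 in NZO/HiLtJ, -0.033 in NOD/ShiLtJ). In C57BL/6J, r was 0.227 to 0.295 in lines 2, 1, 5-1 and 44 and 0.089 in line 4. The fit with the line as a block was run as an alternative. Other alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a filter at 1 CPM in 5 libraries, only the strains compared, no strain term, leaving out each strain, covariates for the fibroblast list and for Y-linked genes, and leaving out each library in turn. Runs without chromosome 8 genes, without NOD/ShiLtJ, without doubted libraries or with the endoderm list as a covariate were chosen after seeing the data.

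Tests were tried on simulated counts. For DE against EpiSC over 20907 genes, 79.7% of genes changed 4-fold were recovered and 52.5% of those changed 2-fold. For PWK/PhJ against C57BL/6J the recovery of 4-fold changes was 72.7% in EpiSC over 17868 genes and 55.4% in DE over 19290 genes. For the difference of that contrast between cell types it was 46.4% over 20907 genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.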

Results

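The libraries comprised 17 of EpiSC and 17 of CXCR4-sorted definitive endoderm. In EpiSC there were 5 lines of C57BL/6J, 3 of PWK/PhJ, 2 each of NOD/ShiLtJ, NZO/HiLtJ, WSB/EiJ and CAST/EiJ, and 1 of DBA/2J. In DE there were 5 of C57BL/6J, 4 of PWK/PhJ, 2 each of NOD/ShiLtJ, NZO/HiLtJ and WSB/EiJ, and 1 each of CAST/EiJ and DBA/2J. Lines of C57BL/6J and DBA/2J are named by numbers, and lines of the other strains by AC or WM and a number. If these series differed in origin or handling, that could not be told apart from strain. The comparisons ask what differs between endoderm and its parent lines, and whether genetic background changes expression in either state. Median depth was 27.7 M counts (M for mega) in EpiSC and 28 M in DE.

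Endoderm genes were strongly higher in DE than in EpiSC. Sox17, a transcription factor of definitive endoderm (chromosome 1, 4490931 to 4497354), rose from 7.49 ± 8.18 CPM (SD, n = 17) to 1020 ± 319 CPM (SD, n = 17), a log2 fold of 7.65 ± 0.38 (SE). It was higher in DE in 16 of 16 lines with both libraries. Hhex, a homeobox gene of anterior endoderm (chromosome 19, 37434810 to 37440731), rose by 5.48 ± 0.25, the BMP and Nodal antagonist Cer1 by 6.54 ± 0.46 and Gata6 by 5.65 ± 0.31 on the log2 scale. Of 18 definitive endoderm genes, 16 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 9.13e-07, and adjusted p = 0.216 with an estimated correlation). Cxcr4, which encodes the receptor used for the sort, rose by 3.26 ± 0.34 and is no independent evidence of the endoderm state. Foxa2 rose by 0.75 ± 0.23, a call that ended without a strain term (0.51) and without the C57BL/6J libraries (0.53).

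Pluripotency genes were lower in DE. Pou5f1 (chromosome 17, 35506018 to 35510772), a core factor of pluripotency, fell from 581.8 ± 92.9 CPM (SD, n = 17) to 11.17 ± 21 CPM (SD, n = 17), and its log2 fold was -6.84 ± 0.49 (SE; adjusted p = 1.47e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Sox2 had a log2 fold of -5.53 ± 0.57, Nanog of -3.42 ± 0.32 and the growth factor gene Fgf4 of -6.10 ± 0.60. Of 12 core pluripotency genes 11 fell, and Sall4, a zinc finger factor, rose by 1.46 ± 0.16 (camera adjusted p = 3.19e-04, and adjusted p = 0.187 with an estimated correlation). Among 13 primed epiblast genes 9 fell and 4 rose (camera adjusted p = 0.182), with Foxd3 at -9.27 ± 0.51, Fgf5 at 2.46 ± 0.10 and Otx2 at 1.96 ± 0.14.

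Signalling and epithelial genes differed as well. Of 10 Nodal targets, 8 rose and 2 fell (camera adjusted p = 0.00543, and adjusted p = 0.216 with an estimated correlation), with the antagonist Lefty1 at 5.49 ± 0.29. Of 12 primitive streak genes, 9 rose and 3 fell (camera adjusted p = 0.0323, and adjusted p = 0.36 with an estimated correlation), among them Gsc at 5.90 ± 0.33 and Mixl1 at 3.41 ± 0.34. Of 11 FGF and ERK targets, 10 fell and 1 rose (camera adjusted p = 0.0161, and adjusted p = 0.216 with an estimated correlation), including the feedback inhibitor Spry2 at -5.64 ± 0.23. Of 12 epithelial genes, 8 rose and 1 fell (camera adjusted p = 0.0323, and adjusted p = 0.5 with an estimated correlation), and the keratin gene Krt8 rose by 4.61 ± 0.37. All 12 interferon response genes fell (camera adjusted p = 0.0147, and adjusted p = 0.5 with an estimated correlation). Beside these, 12 of 15 fibroblast markers fell, or 13 adjusted over the list alone, as in Thy1 at -7.59 ± 0.49, and EpiSC were grown on fibroblast feeders. The ranked genes outside the lists included the forkhead gene Foxq1 (7.17 ± 0.34) and Cacng7 (-9.82 ± 0.42). Among 13 Wnt targets 7 rose and 6 fell (median log2 fold 0.83, mean -0.09, camera direction down and not called), with Dkk1 at 5.55 ± 0.41 and Axin2 at -4.54 ± 0.38.

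The other lists were not called by camera. Genes that rose and fell numbered 1 and 4 of 9 for naive pluripotency, 6 and 0 of 10 for extraembryonic endoderm, 5 and 5 of 13 for mesoderm (5 and 7 adjusted over the list alone; median log2 fold -0.84, mean 0.62), 1 and 5 of 8 for neuroectoderm (2 and 5 adjusted over the list alone), 4 and 2 of 11 for BMP targets and 2 and 7 of 10 for mesenchymal genes. They numbered 3 and 9 of 15 for cell cycle, 8 and 3 of 12 for glycolysis and hypoxia, 9 and 0 of 12 for cholesterol synthesis (10 and 1 adjusted over the list alone), 4 and 2 of 10 for immediate early and heat shock genes and 4 and 5 of 11 for p53 targets. They numbered 5 and 11 of 20 for imprinted genes, 0 and 8 of 12 for MHC class I and 0 and 3 of 6 for sex-linked genes. Across all genes, 16148 of 20907 passed edgeR's quasi-likelihood test, 7805 higher and 8343 lower in DE, with 4703 and 5832 of them changed at least 2-fold. In all, 7 lists were called by camera and 0 with an estimated correlation. The library kit differed between the cell types, so each of these differences is also one between kits.

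**Figure D1:**
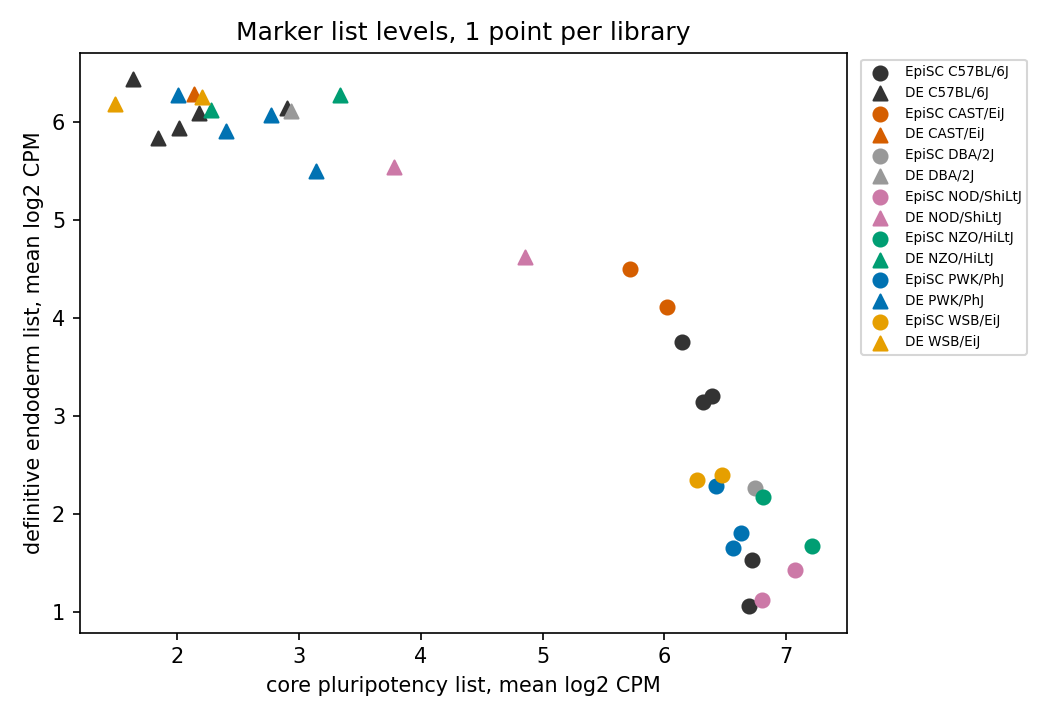
Mean log2 CPM of the definitive endoderm list (vertical axis) against that of the core pluripotency list (horizontal axis), with 1 point per library, circles for EpiSC, triangles for DE and colours for strains. The NOD/ShiLtJ DE libraries had the highest core pluripotency levels in DE, 3.78 in AC595 and 4.86 in AC576, and the next was 3.34 in NZO/HiLtJ line AC653.

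Counts of many genes differed between strains in both cell types. Reads of all strains were aligned to mm10, so strain differences in alignment cannot be told apart from differences in expression. The F test over 5 strains called 7152 of 17868 genes in EpiSC (40%) and 4294 of 19290 in DE (22.3%). On simulated counts changed in PWK/PhJ alone, it recovered 82.7% of 4-fold changes in EpiSC and 48.7% in DE. For 2-fold changes the recovery was 47.1% and 5.48%. Ranked genes in EpiSC included mt-Nd3, the phospholipase gene Plcg2 (chromosome 8, 117498291 to 117635142) and the collagen-modifying P3h2 (chromosome 16, 25959288 to 26105784). Those in DE included Hbld2, Ccdc85c and the tetraspanin gene Cd151. Also ranked were Cwc22, Vcp-rs, Rpl35a and Dynlt1f, which share sequence with copies, so their values are uncertain. The median share of variance between strains was 40.6% in EpiSC and 21.9% in DE, and the biological coefficient of variation was 0.241 and 0.443. The kit also differed between the cell types, so the lower count and share in DE do not show smaller strain effects there. Without NOD/ShiLtJ, a choice made after seeing the data, 3054 genes were called in DE. With the fibroblast list as a covariate the DE count was 2833.

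Mean levels of 12 of the 48 lists and cell types differed between strains by permutation test. In EpiSC the neuroectoderm list was highest in C57BL/6J at 0.74 ± 0.07 (SD, n = 5) and lowest in PWK/PhJ at -0.58 ± 0.16 (SD, n = 3) on the log2 CPM scale (adjusted p = 0.0048, permutation test). The oligodendrocyte lineage gene Olig1, outside that list, had 4657 counts summed over the C57BL/6J EpiSC libraries against 3 in NOD/ShiLtJ, 5 in NZO/HiLtJ, 9 in PWK/PhJ and 6 in WSB/EiJ. The naive pluripotency, cell cycle and p53 target lists also differed in EpiSC (adjusted p = 0.0321 for each, permutation test). In DE the Nodal target list was highest in C57BL/6J at 8.94 ± 0.28 (SD, n = 5) and lowest in NOD/ShiLtJ at 7.96 ± 0.37 (SD, n = 2; adjusted p = 0.0321, permutation test). The core pluripotency, fibroblast, Wnt target, mesenchymal, p53 target, imprinted and interferon lists differed too (adjusted p from 0.0321 to 0.0476, permutation test). The definitive endoderm list in DE did not pass (unadjusted p = 0.0388, permutation test). The count of 12 fell to 2 without the EpiSC library of PWK/PhJ line AC698 and to 4 without the DE library of NOD/ShiLtJ line AC576 or of C57BL/6J line 4 or 1. It was 5 without the DE library of AC698, 6 without that of AC699, AC705 or 44, and 7 without that of WSB/EiJ line AC635 or AC627.

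In EpiSC, PWK/PhJ lines differed from C57BL/6J lines in glycolytic genes and in genes outside the lists. Htr7, a serotonin receptor gene (chromosome 19, 35958734 to 36057507), was at 132.1 ± 9.25 CPM (SD, n = 3) in PWK/PhJ and 1.08 ± 0.418 CPM (SD, n = 5) in C57BL/6J, a log2 fold of 6.93 ± 0.37. Stap2 (4.09 ± 0.18), Rps6kl1 (4.07 ± 0.22) and the homeobox gene Msx1 (3.28 ± 0.33) were higher, and Wdr31 (-5.10 ± 0.29), Slc35d3 (-5.09 ± 0.33) and Trh (-3.79 ± 0.78), the gene of a releasing hormone on the endoderm list, were lower. Of 12 glycolysis and hypoxia genes, 8 fell, or 9 adjusted over the list alone (camera adjusted p = 0.000624, and adjusted p = 0.947 with an estimated correlation). Among them were the glycolytic enzyme genes Ldha (-1.25 ± 0.14), Eno1 (-1.02 ± 0.09) and Pgk1 (-1.05 ± 0.10). The mean level of the glycolysis and hypoxia list in EpiSC did not pass across the 5 strains (adjusted p = 0.0524, permutation test). Of 11 p53 targets, 7 rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.307), with the cell cycle inhibitor gene Cdkn1a at 0.93 ± 0.19. Pou5f1 had a log2 fold of 0.20 ± 0.11 and Sox17 of -1.08 ± 0.78, neither past the test. None of 15 fibroblast markers passed, and their median log2 fold was 1.24.

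In all 5330 genes passed edgeR's quasi-likelihood test, 2445 higher and 2885 lower in PWK/PhJ EpiSC. The count was 3457 without PWK/PhJ line AC698, 3532 without AC695 and 3245 with Y-linked genes as a covariate, where Cdkn1a (0.68) no longer passed. Summed Y-linked genes were at 7.89 to 8.24 log2 CPM in PWK/PhJ EpiSC, above the 5.42 to 7.82 of C57BL/6J EpiSC. That covariate therefore largely follows the strain, and the run with it cannot fully tell Y-linked level from strain. The number of lists called by camera was 2 without C57BL/6J line 5-1, against 1.

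In DE, the mesenchymal list was higher in 3 of 4 PWK/PhJ lines than in any C57BL/6J line, while Sox17, Cxcr4 and Foxa2 did not pass the test. Sox17 had a log2 fold of -0.02 ± 0.22, Cxcr4 of 0.42 ± 0.22 and Foxa2 of 0.46 ± 0.24 (n = 4 and 5). Of 18 definitive endoderm genes 2 fell, among them Trh at -5.62 ± 0.90. The Nodal target Lefty1 (-1.40 ± 0.29) fell, and Nanog (chromosome 6, 122707489 to 122714633) rose by 2.00 ± 0.41. Of 10 mesenchymal genes, 7 rose (camera adjusted p = 0.0261, and adjusted p = 0.925 with an estimated correlation), among them Zeb2 at 3.06 ± 0.78 and the fibronectin gene Fn1 at 1.70 ± 0.30. The list was at 4.88, 5.07 and 5.50 log2 CPM in PWK/PhJ lines AC698, AC705 and AC699 and at 3.68 in AC695, against 3.00 to 3.68 in C57BL/6J. The calls for Snai2 (2.62 ± 0.76) and Vim (1.69 ± 0.51), also among the 7, ended without AC699 (2.45 and 1.13), AC698 (2.66 and 1.76), AC705 (2.44 and 1.73), 44 (2.58 and 1.53), 4 (2.4 and 1.59) or 1 (2.51 and 1.53). Beside these, 4 of 14 fibroblast markers rose, or 9 adjusted over the list alone (camera adjusted p = 0.00165, and adjusted p = 0.925 with an estimated correlation). Of 20 imprinted genes, 6 fell and 1 rose, or 6 and 3 adjusted over the list alone, with the paternally expressed Mest (chromosome 6, 30723547 to 30748465) at -2.62 ± 0.39. The ranked genes included Fhl3 (5.49 ± 0.35; chromosome 4, 124700701 to 124708611), Cldn4, a tight junction gene (5.61 ± 0.65), and the proteasome gene Psmb10 (-5.16 ± 0.57). Prg2 had 9 counts summed over PWK/PhJ against 5380 over C57BL/6J, and Prkcq 14 against 3248. Values of Dynlt1f, Srp54c, Hist1h4d and Prss1, also ranked, are uncertain because copies share their sequence.

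Here 3303 genes passed edgeR's quasi-likelihood test, 1863 higher and 1440 lower in PWK/PhJ DE, and 2017 with the fibroblast list as a covariate. Under that covariate Nanog (2.04), Zeb2 (1.14), Fn1 (1.15), Snai2 (0.40) and Vim (0.05) no longer passed. Camera called 1 list without the DE library of line AC699, 2 or 44 and 5 without that of line 5-1, against 2. Line AC699 had summed Y-linked genes at 2.75 log2 CPM, against 7.89 to 8.32 in the other PWK/PhJ DE libraries, and has no EpiSC library. With Y-linked genes as a covariate 3255 genes passed.

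The PWK/PhJ effect differed between the cell types for 1394 genes by the interaction test, 829 higher and 565 lower in DE, and for 798 with the cell line as a block. The share higher in DE was 59.5%, but 52.8% with RLE scaling and 54% with DESeq2. Mcc, a negative regulator of the cell cycle (chromosome 18, 44425060 to 44812182), had a difference of 5.83 ± 0.48 on the log2 scale, with PWK/PhJ below C57BL/6J in EpiSC (5.22 ± 1.40 against 63.5 ± 22 CPM; SD, n = 3 and 5) and above it in DE (11.3 ± 3.64 against 2.43 ± 0.715 CPM; SD, n = 4 and 5). Itpk1, an inositol phosphate kinase gene (chromosome 12, 102568582 to 102704930), had a difference of -4.17 ± 0.29, and Cldn4 of 7.40 ± 1.34. Lefty2, a Nodal target, was higher in PWK/PhJ EpiSC (1.75 ± 0.42) and lower in PWK/PhJ DE (-1.77 ± 0.42), a difference of -3.50 ± 0.63. Its EpiSC call ended with Y-linked genes as a covariate (1.53), which largely follows the strain in EpiSC. Its DE call ended with the fibroblast covariate (-1.68). The difference for Trh was -1.81 ± 1.06 and did not pass. The count of 1394 was 811, 814 and 842 without the EpiSC libraries of PWK/PhJ lines AC695, AC705 and AC698. The library kit differed between the cell types, so each difference of a strain effect between them is also one between kits.

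Over all 5 strains, the effect of strain differed between cell types for 2227 genes, or 1104 with the cell line as a block and 1452 without the EpiSC library of NOD/ShiLtJ line AC576. As for PWK/PhJ, this cannot be told apart from a difference between kits. Ranked genes were the Mediator subunit gene Med18 (chromosome 4, 132458731 to 132463921), the heat shock factor gene Hsf2 (chromosome 10, 57486385 to 57513135), Fhl3, Itpk1, Arhgap27 and Ccdc85c.

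The PWK/PhJ folds of the cell types were correlated across 16573 genes, which are not independent replicates (Pearson 0.643, Spearman 0.469, covariance 1.201). Of 1610 genes called in both, 832 were higher and 662 lower in both and 116 were opposite, so 92.8% had the same direction. Independent lists would share 229.7 higher and 208.9 lower genes. When strain labels of the lines were exchanged in both cell types together (99 relabellings), the median Pearson correlation was 0.205 and the median covariance 0.055. The highest were 0.646 and 0.931. The highest Pearson correlation came from labelling C57BL/6J lines 2, 44, 5-1 and 1 as PWK/PhJ. That nearly swaps the strains, and a full swap leaves the correlation as it was. Most lines are in both fits, and differences of alignment between strains would recur in both cell types. With no line in both cell types the Pearson correlation was 0.564.

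**Figure D2:**
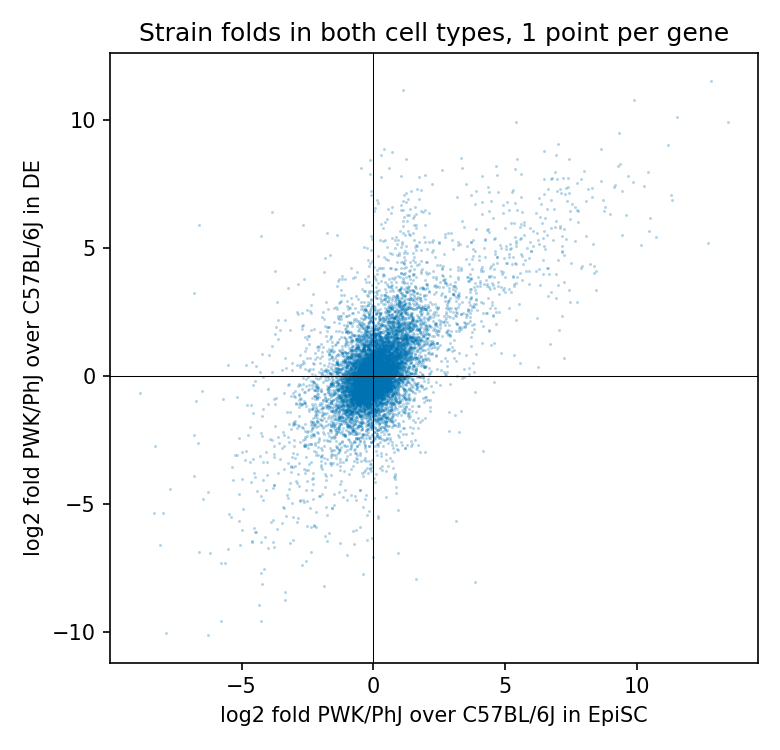
Log2 fold of PWK/PhJ over C57BL/6J in DE (vertical axis) against that in EpiSC (horizontal axis), with 1 point per gene tested in both. Most genes lie near 0 on both axes, and the Pearson correlation was 0.643.

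In NOD/ShiLtJ DE, most called pluripotency, fibroblast and interferon genes were higher than in C57BL/6J DE, and most called endoderm genes were lower. The mean level of the definitive endoderm list in DE did not pass across strains (adjusted p = 0.0887, permutation test). Pou5f1 was at 58.0 ± 47.0 CPM (SD, n = 2) against 3.48 ± 5.00 CPM (SD, n = 5), a log2 fold of 4.08 ± 0.85, and 7 of 12 core pluripotency genes rose and 2 fell, or 8 and 2 adjusted over the list alone. Of 18 definitive endoderm genes, 12 fell and 1 rose, with Cer1 at -2.39 ± 0.51 and Gata6 at -1.48 ± 0.29, while Cxcr4 was at -0.31 ± 0.29 and did not pass. Of 14 fibroblast markers, 12 rose, or 13 adjusted over the list alone, with the collagen gene Col1a1 at 4.42 ± 0.87 (chromosome 11, 94936224 to 94953042). Of 11 interferon response genes, 7 rose, with Isg15 at 5.49 ± 1.33, and 7 of 12 MHC class I genes rose (9 of each adjusted over the list alone), with B2m, the light chain gene, at 2.62 ± 0.45. The mesenchymal list was at 5.58 ± 0.34 log2 CPM (SD, n = 2) against 3.41 ± 0.27 (SD, n = 5) in C57BL/6J DE. The mesoderm (1.60 against -0.52) and BMP target (4.28 against 2.03) lists were higher too. Neither of these 2 passed across strains (adjusted p = 0.148 and 0.076, permutation test). Ranked genes were Acta1 (8.35 ± 0.93), Cryab (6.35 ± 1.10), Trh (-4.31 ± 1.15) and Ermn (-4.30 ± 0.75). In all 2191 genes passed edgeR's quasi-likelihood test, 1539 higher and 652 lower. Without NOD/ShiLtJ line AC576 the count was 406 and Pou5f1 (2.85), Cer1 (-1.80), Gata6 (-1), Col1a1 (3.71) and Isg15 (3.62) no longer passed. With the fibroblast list as a covariate 31 genes were called, and the calls for Cer1 (-2.14), Gata6 (-1.25), Pou5f1 (1.20), Isg15 (1.92) and B2m (0.57) ended, as did that for Col1a1, a member of that list, which turned to -0.22. The NOD/ShiLtJ DE libraries had the fibroblast list at 4.21 and 4.27 log2 CPM, and the other DE libraries had it at 3.05 or lower. That covariate therefore nearly follows the strain, and the run with it cannot tell fibroblast content from strain. The count of calls with only the strains compared was 1202.

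In NOD/ShiLtJ EpiSC 2309 genes were called, 1069 higher and 1240 lower, including 6 of 11 p53 targets higher, and Pou5f1 was at -0.03 ± 0.13. The neurofilament gene Nefm rose by 3.84 ± 0.32 (chromosome 14, 68082590 to 68124846). The count was 848 without line AC576, 621 with Y-linked genes as a covariate and 284 with only the strains compared. Summed Y-linked genes were at 8.28 and 8.31 log2 CPM in these lines, above the 5.42 to 7.82 of C57BL/6J EpiSC. The run with that covariate therefore cannot fully tell Y-linked level from strain.

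NZO/HiLtJ and WSB/EiJ differed from C57BL/6J in both cell types. In WSB/EiJ DE, Cxcr4 (chromosome 1, 128588199 to 128592293) rose by 2.53 ± 0.26 and the Wnt effector gene Lef1 by 3.44 ± 0.43, while Tdgf1, the Nodal co-receptor gene, was at -3.05 ± 0.36 (n = 2 and 5). Sox17 was at 0.08 ± 0.28 and did not pass. In WSB/EiJ EpiSC Nefm rose by 4.73 ± 0.32. In NZO/HiLtJ DE, Trim25 (6.25 ± 0.79) and the sulfotransferase gene Chst2 (5.07 ± 0.50) rose and Pilra was at -5.51 ± 0.81, and in NZO/HiLtJ EpiSC Arhgap45 rose by 3.28 ± 0.23. WSB/EiJ gave 1324 calls in EpiSC and 439 in DE, and NZO/HiLtJ 986 and 272. The share of the DE calls that was higher in the strain was 52.2% for WSB/EiJ and 65.1% for NZO/HiLtJ with edgeR, and 41.5% and 51% with DESeq2. For WSB/EiJ these were 526 and 135 without line AC627, and 566 and 168 without AC635. For NZO/HiLtJ they were 242 and 84 without line AC653, and in EpiSC 263 without AC671 and 1718 without C57BL/6J line 2.

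CAST/EiJ was compared in EpiSC alone. The carbonic anhydrase gene Car2 (chromosome 3, 14886273 to 14900770) had a log2 fold of -8.25 ± 0.24 and the taste receptor gene Tas1r1 rose by 6.68 ± 0.32 (n = 2 and 5). Of 17 definitive endoderm genes 7 rose, or 9 adjusted over the list alone, with Foxa2 at 1.89 ± 0.45, and 6 of 12 core pluripotency genes fell and 1 rose, with Fgf4 at -1.63 ± 0.38. In all 5652 genes were called, 2595 higher and 3057 lower, and 3359 with only the strains compared, where Foxa2 (1.90) passed and Cer1 (3.00), Cxcr4 (2.41) and Gata6 (1.95), also among the 7, did not. Those calls ended too without WM080 (3.11, 2.61 and 2.06) and without WM078 (2.88, 2.18 and 1.83). Without line WM080 the count was 2826 and Fgf4 (-1.64) did not pass, and without WM078 it was 3296 and neither Fgf4 (-1.63) nor Foxa2 (1.65) passed.

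Levels of chromosome 8 genes, Xist and fibroblast markers also differed between libraries of a cell type. In the DE library of C57BL/6J line 5-1, 506 genes of chromosome 8 had a median deviation of 0.52 (log2) from the median DE library, and in the other DE libraries the median lay between -0.18 and 0.00. In EpiSC, Xist, the noncoding RNA of X inactivation, ran from 0.56 log2 CPM in C57BL/6J line 1 to 5.91 in NOD/ShiLtJ line AC595. The fibroblast list was at 0.87 and 5.59 log2 CPM in the same libraries.

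**Figure D3:**
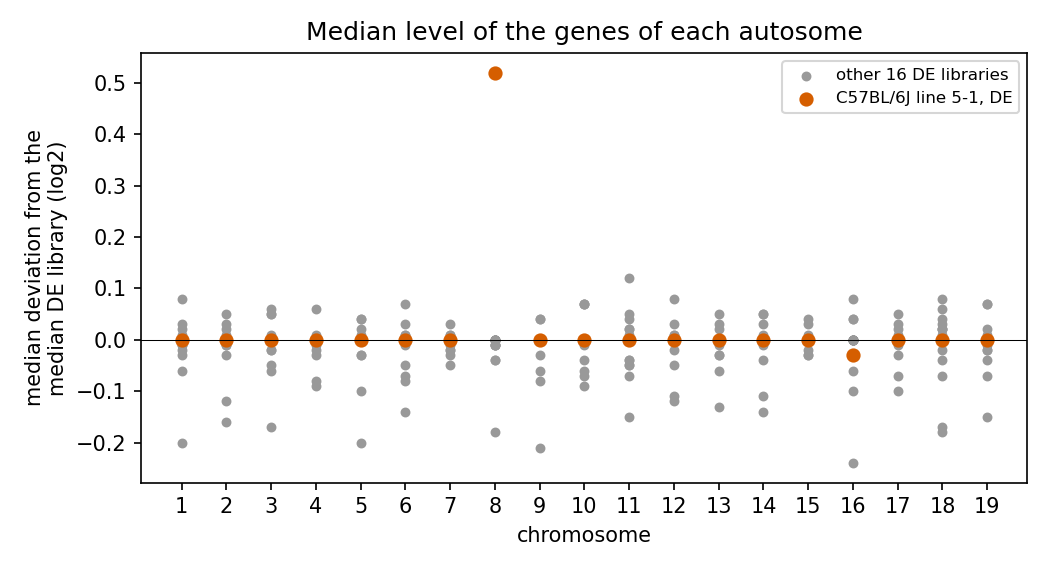
Median deviation of the genes of each autosome from the median DE library (vertical axis, log2) by chromosome (horizontal axis), with 1 point per DE library and line 5-1 of C57BL/6J in orange. On chromosome 8 that library lies at 0.52.

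**Figure D4:**
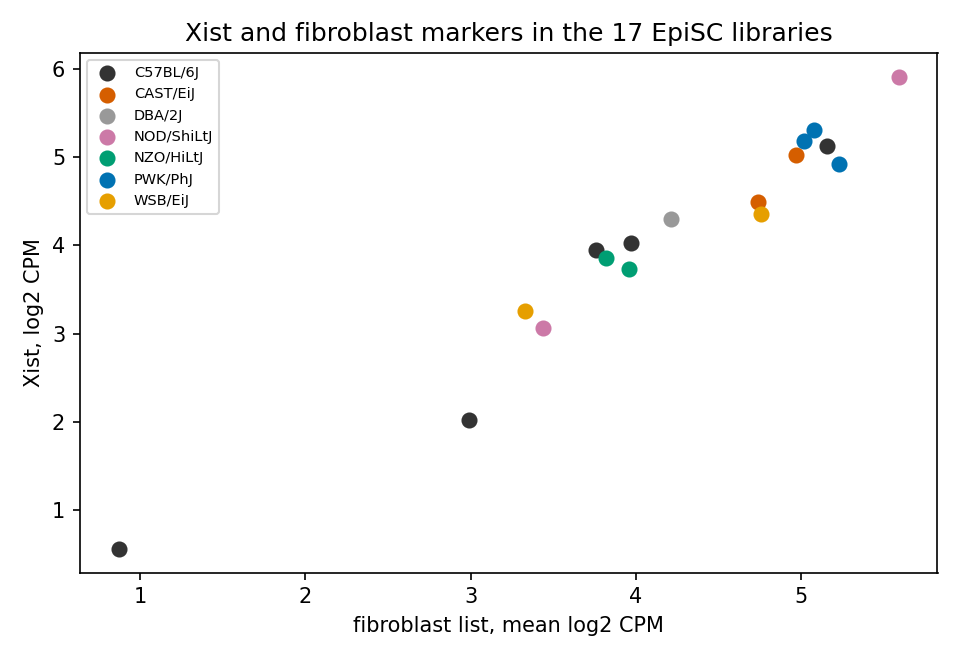
Xist (vertical axis, log2 CPM) against the mean of the fibroblast list (horizontal axis, log2 CPM) in EpiSC, with 1 point per library coloured by strain. Xist runs from 0.56 to 5.91.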

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

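The tests of chromosome 8, of the fibroblast and interferon parts of the NOD/ShiLtJ pattern and of Xist were chosen after the results were seen, and the bound of the fibroblast test was restated after its value was known.

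In 14 of 215 tests of groups of 4 or 5 libraries, 1 library lay far from the others; chance marks about 1 in 20 groups. In C57BL/6J EpiSC, on the log2 CPM scale, Foxa2 was at 4.14 in line 5-1 (others 5.35 to 5.74), Olig1 at 1.92 in line 44 (others 5.05 to 5.68) and Nr5a2, with few counts, at -3.22 in line 4 (others -2.20 to -1.92). In C57BL/6J DE, line 2 had the MHC class I list at 3.11 (others 1.60 to 1.88), the interferon list at 0.84 (others -0.73 to -0.58), Pou5f1 at 3.64 (others -0.13 to 0.92) and Gprc5a at 3.85 (others 5.51 to 6.14). Line 5-1 had Lefty2 at 8.27 (others 10.54 to 11.01), and line 44 had Car3 at -2.90 (others -0.27 to 0.78). In PWK/PhJ DE, line AC705 had a log2 total count of 25.80 (others 24.54 to 24.62) and Cldn4 at 4.24 (others 5.46 to 5.63). Line AC699 had the sex-linked list at 0.29 (others 2.76 to 3.01) and Lefty2 at 7.71 (others 8.84 to 9.02).

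The PWK/PhJ effect differed between DE and EpiSC by the interaction test for 26 of 70 named genes, against 6.67% of all 20907 genes tested. Of the 26, 10 were named because this difference was among the largest called and others for large folds in 1 cell type, so the tally says nothing about genes in general. The difference (DE minus EpiSC, log2) was higher in DE for Cldn4 (7.40), Pim1 (6.59), Wnt8a (6.21), Trp73 (5.92), Mcc (5.83), Fhl3 (5.62), Acta1 (4.73), Evx1 (4.39), Clca4a (4.37), Susd2 (3.81), Slc39a8 (3.67), Car3 (3.33) and Tdgf1 (1.79). It was lower in DE for Prkcq (-7.02), P3h2 (-4.66), Chga (-4.34), Itpk1 (-4.17), Lmo1 (-4.14), Ntrk2 (-4.05), Htr7 (-3.96), Lefty2 (-3.50), Meg3 (-2.30) and Mest (-1.78), and for Hist1h4d (-5.14), Srp54c (-2.62) and Dynlt1f (-1.53), whose reads are shared with copies. Trp73, Wnt8a, Lmo1, Prkcq, Evx1 and Htr7 had few counts in a group, so their sizes depend on the prior count. The call for Wnt8a ended without the EpiSC library of PWK/PhJ line AC695 (6.03) or AC705 (6.09).

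The DE library of C57BL/6J line 5-1 had high levels of genes on chromosome 8. Over 506 genes the median deviation from the median DE library was 0.52 on the log2 scale, with 90.5% of genes above 0 against 47.1% elsewhere, while the next highest DE library was at 0.00 and EpiSC of the same line at 0.03. A bias by GC content, gene length or level was argued against, since the median after a fit on these was 0.57. Extra copies of chromosome 8 in many of the cells may be the source: every 20 Mb window was raised, the lowest at 0.46. The call counts in DE without chromosome 8 genes stayed within 1.5 times.

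NOD/ShiLtJ DE had higher pluripotency, fibroblast and interferon genes. Its mesenchymal, mesoderm and BMP target lists were also higher than in C57BL/6J DE, the last 2 not past the test across strains. Explanations for these 3 lists were not tested. A single share of undifferentiated cells was argued against as the whole cause of the pluripotency part, because the share implied by each of 121 genes lay within 3-fold of the median share (5.80%) for 30.6%, and 24.0% were lower in NOD/ShiLtJ DE than in C57BL/6J DE; EpiSC levels come from another kit, whose effect on that spread was not tested. For the fibroblast part this explanation cannot be told apart from others, since the list lay -0.27 from EpiSC of the same lines on average, at 0.83 in AC576 and -1.38 in AC595. Fibroblast RNA could carry the interferon part: over 15 DE libraries of other strains the lists rose together (Pearson 0.782, permutation p = 0.00028, adjusted p = 3.73e-04; Spearman 0.846, permutation p = 1e-04, adjusted p = 2e-04; Pearson 0.748 without the 2 farthest libraries; 4 relations tested). In those 15 libraries the interferon list ran only from -0.92 to 0.97 log2 CPM. It was at 2.16 and 3.43 in NOD/ShiLtJ lines AC595 and AC576, whose fibroblast list was at 4.21 and 4.27. Whether fibroblast RNA is enough for those levels was not tested. Strain remains open and untested, with 2 lines.

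Xist differed between EpiSC libraries. Female lines were argued against, since Xist did not fall as the summed Y-linked genes rose (17 libraries, Pearson 0.185, permutation p = 0.451, adjusted p = 0.451; Spearman 0.265, permutation p = 0.302, adjusted p = 0.302; Pearson 0.355 without the 2 farthest). RNA of feeder fibroblasts may be the source, as Xist rose with the fibroblast list (Pearson 0.976, permutation p = 1e-05, the smallest possible, adjusted p = 2e-05; Spearman 0.953, permutation p = 1e-05, adjusted p = 4e-05; Pearson 0.950 without the 2 farthest). No biological explanation beyond sex was tested.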

How the results depend on the processing

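Every alternative was planned except the runs without chromosome 8 genes, without doubted libraries, without NOD/ShiLtJ or with the endoderm list as a covariate, which were chosen after the data were seen and moved no count by over 1.5 times. RLE scaling and the filter at 1 CPM moved none either. Where a value below differs, the cause was not tested unless stated. Without a filter on low counts, calls numbered 6782 for strain in DE, 3342 for NOD/ShiLtJ, 1054 for NZO/HiLtJ and 1241 for WSB/EiJ in DE, 2150 for the difference of the PWK/PhJ effect between cell types and 4155 for strain by cell type. With only the strains compared, which leaves fewer libraries for the spread, they numbered 284 (NOD/ShiLtJ), 201 (NZO/HiLtJ), 367 (WSB/EiJ) and 3359 (CAST/EiJ) in EpiSC and 1202 (NOD/ShiLtJ), 69 (NZO/HiLtJ) and 227 (WSB/EiJ) in DE. Spread also differed between strains in EpiSC. The chi-square per degree of freedom between libraries was 29.1 to 95.2 in C57BL/6J and 6.57 to 12 in PWK/PhJ. It was 7.83 in NZO/HiLtJ, 16 in CAST/EiJ, 27.7 in WSB/EiJ and 71.8 in NOD/ShiLtJ. How far this unequal spread accounts for the lower counts was not tested. With Y-linked genes as a covariate calls numbered 621 for NOD/ShiLtJ and 3245 for PWK/PhJ in EpiSC, where that covariate largely follows the strain. With the fibroblast list as a covariate they numbered 2833 for strain, 31 for NOD/ShiLtJ and 2017 for PWK/PhJ in DE, and in NOD/ShiLtJ DE the folds of the collagen genes Col1a1 and Col3a1, members of that list, turned to -0.22 and -1.88. DESeq2 called 1817 genes for NZO/HiLtJ in EpiSC, 731 for NZO/HiLtJ and 955 for WSB/EiJ in DE and 3849 for strain by cell type. Camera with an estimated correlation called 0 lists in each of 3 contrasts, and fry, which asks whether a list's genes move on balance, called 22 for DE against EpiSC, 7 for PWK/PhJ in EpiSC and 4 in DE. Over only the genes called in EpiSC, the correlation of the PWK/PhJ folds was 0.78.

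With the cell line as a block, 798 genes were called for the difference of the PWK/PhJ effect and 1104 for strain by cell type, with 15676 for DE against EpiSC and 7 lists; the ranked or listed genes that were run with the block kept their calls, which other genes did not all do.

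Leaving out 1 library or line at a time gave 15801 to 16093 calls for DE against EpiSC, 5248 to 8219 for strain in EpiSC and 2943 to 5295 in DE. It gave 3457 to 6368 for PWK/PhJ in EpiSC and 2334 to 3795 in DE, 848 to 3433 and 406 to 3063 for NOD/ShiLtJ, 242 to 1718 and 84 to 352 for NZO/HiLtJ, 526 to 1425 and 135 to 558 for WSB/EiJ, and 2826 to 5933 for CAST/EiJ. It gave 811 to 1964 for the difference of the PWK/PhJ effect, 1452 to 3190 for strain by cell type, 0.605 to 0.646 for the correlation of folds, 2 to 15 list levels, and 1 to 2 lists for PWK/PhJ in EpiSC and 1 to 5 in DE. Where that leaves a strain with 1 library, that library is assumed to vary like the other groups. Depth limits genes with few counts, whose folds rest on the prior count.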

Other observations

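The test of the interferon list against the fibroblast list in EpiSC and the splits made by exchange within lines were chosen after the data were seen; the counts of other splits of the samples were planned.

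In the 17 EpiSC libraries the interferon list rose with the fibroblast list too (Pearson 0.841, permutation p = 1e-05, adjusted p = 2e-05; Spearman 0.787, permutation p = 0.00029, adjusted p = 3.87e-04; Pearson 0.730 without the 2 farthest libraries). The PWK/PhJ DE library of line AC699 had Xist at 3.13 and the summed Y-linked genes at 2.75 on the log2 CPM scale, where the other PWK/PhJ DE libraries had Y-linked sums of 7.89 to 8.32.

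For each count of genes below, no other split of the samples that was drawn called as many as the real one. With 50, 56 or 100 splits, the lowest share that could be reached was 1 in 50, 1 in 56 or 1 in 100. Chance is not excluded beyond that. For DE against EpiSC, 1 of 100 splits, the real one, called as many genes (16148, highest other 854). Those other splits mostly mixed the lines, so the real split was also set beside splits that part all 16 pairs, made by exchanging the cell types within some lines. Of 100 such splits 1, the real one, called as many, and the highest other (9267) exchanged 3 pairs and left the rest as they are. For PWK/PhJ against C57BL/6J, 1 of 56 splits in EpiSC (5330, highest other 3477) and 1 of 100 in DE (3303, highest other 2127) called as many. The same held for the difference of that contrast between cell types (1 of 50 splits, 1394, highest other 838), for strain in EpiSC (1 of 100, 7152, highest other 514), strain in DE (1 of 100, 4294, highest other 182) and strain by cell type (1 of 50, 2227, highest other 8). For the correlation of the PWK/PhJ folds, 2 of 100 relabellings reached 0.643, the highest other being 0.646. The highest other splits of the PWK/PhJ results gave the PWK/PhJ label to C57BL/6J lines alone. In DE, for the difference and for the correlation these were 4 lines, so that 1 C57BL/6J line stayed with the PWK/PhJ lines. In EpiSC alone they were lines 4, 1 and 44, whose definitive endoderm list was at 3.15 to 3.76 log2 CPM, against 1.53 and 1.06 in lines 2 and 5-1 and 1.65 to 2.29 in PWK/PhJ; whether that accounts for the 3477 calls was not tested.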
